A study of Mus musculus with 27 samples.

How the data were processed

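The deposited files are the scanner output of 27 two-colour Agilent arrays, 1 per hybridisation, and a table of 844 probes for the same arrays. Per the labels, tail tip DNA of each animal was labelled with Cy5 and a reference of the same sex with Cy3, and no dyes were swapped. The channel labels call the reference a pool of female or of male samples, while the series' design text speaks of a single reference animal of each sex; which of them holds is not given in the sources used here. Samples were grouped as the labels give them: 2 APA sires, 2 APA dams, 6 APA offspring, 2 control sires, 2 control dams, 6 control offspring, 3 female and 4 male reference self hybridisations.

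Per the file headers, the authors' arrays were read with Agilent Feature Extraction 10.7.3.1 (10.7 in the submitters' processing notes), with linear dye normalisation, and probe positions are on mm9. Per the file headers, the deposited log ratio is the log10 of Cy5 over Cy3 processed signal, and the processed signals are intensity values after background subtraction, detrending and dye normalisation. The deposited log ratio was checked against the deposited signals and differed by at most 1.4e-06 on the log2 scale. The table of 844 probes holds log2 ratios from the authors; its filter, scale and centring are not given in the sources used here. Set against the scanner values of the same arrays its columns had a slope of 0.979 to 1.01, an intercept of −0.017 to 0.018 and a correlation across probes of 0.965 to 0.998, so its direction was taken as Cy5 over Cy3.

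For the main values the log10 ratios were turned into log2, spots marked as non-uniform or population outliers by the scanner software were left out, control spots were left out, spots of 1 probe were averaged, and each array was centred on the median of its autosomal probes. No loess or quantile normalisation was applied, since true copy number shifts may go one way. Each array gave 43020 non-control spots for 27274 probes (26636 autosomal, 586 on X, 52 on Y) with a median spacing of 4142 bp. Array noise is the interquartile-based SD of differences between neighbouring probes, divided by the square root of 2.

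Segments were found per array by optimal partitioning of the mean with a penalty of 3 times the logarithm of the number of probes of the chromosome, in units of the noise variance, after single probes were pulled in to within 4 SD of the median of 5 neighbours. A call needed at least 5 probes, an absolute mean log2 of at least 0.25 and a mean of at least 6 times its SE. A call was shared by another animal if calls of the same sign covered at least 50% of its probes. It counted as absent from the parents if neither parent shared it and neither parent's mean over its probes reached 50% of the offspring's value with the same sign. On simulated arrays with the noise of the animals, implanted segments of 5 probes were recovered in 18.8% of cases at a log2 of 0.25, in 90.5% at 0.35 and in 95.5% at 0.5. Segments of 10 probes were recovered in 61.5% at 0.25 and in 100% at 0.35 and 0.5, and 0 false calls were made in 10 such arrays. Apart from the implanted segments these arrays held independent noise around 0, so they cannot show calls from probe offsets that real arrays share. The 7 real self hybridisations held 3 calls.

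Neighbouring autosomal probes with gaps of at most 10 kb were joined into 929 regions of at least 2 probes, which took the place of genes, because the scanner files pair probes with positions but not with gene names. For the same reason a test of gene lists fixed beforehand was not run. Probes and region means were tested with limma 3.58.1 (R 4.3.3) with sex as a covariate and the litter as a random block (duplicateCorrelation). Benjamini-Hochberg adjustment was used with a threshold of 0.05. In the main offspring fits the estimated litter correlation was −0.051 for probes and −0.029 for regions. The block therefore made no allowance for likeness of litter mates. With it 1315 probes had an unadjusted p under 0.05, and without it 1034, so the block made the probe test less strict. The offspring comparison used the 12 offspring; sires and dams were compared in a fit of all 20 animals, which borrows the spread of the other groups. Simulated offspring data had a litter correlation of 0.1 and 200 altered features, each shifted in all 6 APA offspring. The fits estimated that correlation at −0.00068 to 0.018. Regions were recovered in 94.5% at a shift of 0.1 and 100% at 0.2 and 0.3, with 12, 13 and 16 false calls. Probes were recovered in 7.5%, 92.5% and 100%, with 5, 24 and 21 false calls. The 200 features were a far larger share of the 929 regions than of the 26636 probes, which eases the adjusted threshold for regions. Recovery when only a few regions are altered was not simulated. The share of false calls among all calls was above the nominal 5% at every shift, for regions and for probes, and was largest for probes at 0.1, with 5 false and 15 recovered.

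Counts per animal, noise and region means of groups were compared with exact permutation tests in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1), two-sided unless stated. Named regions were fixed by rule before the data were examined. If fewer than 3 regions passed, these were the 5 largest differences in each direction among regions of at least 3 probes; for calls they were all calls absent from both parents, up to 15, and the 10 regions called in most animals. Slides were taken as batches: the 27 arrays lay on 7 slides scanned on 6 days, slides held several groups, and the slide was fitted as a term in an alternative. The mean correlation of arrays, after subtracting each probe's median, was 0.140 on one slide and −0.025 between slides. No array repeated another: at most 0.0073% of probes had the same value in a pair of arrays, and the highest correlation of a pair was 0.609, between self hybridisations of the male reference.

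Alternatives were normexp background correction with an offset of 50, subtraction of the same-sex self hybridisations, omission of 66 dim probes, centring on the mode, other fits for litter, family number and slide, other calling thresholds, and leaving out each offspring and each sire in turn; the dams were not left out. normexp was run on the spot medians and local background medians, since spot means were not used here. Subtraction of the same-sex animal median, the joining of adjoining calls, the subtraction of self hybridisations for the parental share and the reassignment of offspring to litters were chosen after the data had been seen.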

Results

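Copy number was measured by two-colour comparative genomic hybridisation in tail tip DNA of 20 C57BL/6J mice, an inbred laboratory strain, on a custom array. The animals formed 4 families. In 2 families the sire was of advanced paternal age (APA, 12 to 16 months), and in the other 2 the sire was a control aged 3 months. Each family held a sire, a dam and 3 offspring, so that there were 6 APA offspring and 6 control offspring, each with 3 females and 3 males. Animal DNA carried Cy5 and a reference of the same sex carried Cy3. A further 7 arrays held a reference hybridised against itself, 3 with the female and 4 with the male reference, and served as the background. The design asked whether offspring of older sires carry more copy number variants than offspring of young sires.

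Each array held 27274 probes with a position on mm9, of which 26636 were autosomal. On every array at least 99.8% of the spots were well above background, and the median processed intensity lay between 938 and 1000.5 for Cy3. The noise between neighbouring probes was 0.0945 to 0.131 on the log2 scale in the animals and 0.0752 to 0.0891 in the self hybridisations. It was 0.107 ± 0.0059 in APA offspring and 0.101 ± 0.0045 in control offspring (SD, n = 6 each), a difference of 0.0051 that lay within the spread (two-sided exact permutation test, p = 0.113); without the control family 1 offspring 1 the difference was 0.0062 and passed the threshold (p = 0.0498), and without the APA family 2 offspring 3 it was 0.0029 (p = 0.229). In the 4 pairs of an APA and a control offspring on one slide, the difference in noise was −0.0030, 0.0049, 0.0040 and 0.00099. Median X log ratios of the animals lay between −0.044 and −0.017, close to the 0 of a reference of the same sex.

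Copy number calls in the 20 animals fell into 17 autosomal regions, of which 9 were called in more than 1 animal. The most frequent was a gain on chromosome 11 from 3026905 to 3054786 (mm9, 52 probes), called in 16 animals. Its mean was also 0.25 ± 0.018 in the 3 female and 0.19 ± 0.021 in the 4 male self hybridisations (SD), and no animal kept a call there once the self hybridisations were subtracted. A gain on chromosome 4 from 41643749 to 42876631 (9 probes) was called in 10 animals, and in 1 after that subtraction. The regions with many probes and a background near 0 lay on chromosome 14: a proximal one from 26694876 to 27123408 (390 probes) and a distal one from 69932605 to 70090346 (429 probes). No gene is named for any region, because the files pair these positions with no gene name and no annotation of mm9 was used here.

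At the proximal chromosome 14 region the log ratio followed sex and family. Of the 10 females, 9 had a mean between 0.32 and 0.35, while the control family 1 offspring 1 was at 0.11. The male animals outside control family 1 lay between 0.070 and 0.10; the call in the APA family 2 offspring 3, a male, covered 5 probes from 26724300 to 26725196 at 0.44. The control family 1 sire was at −0.41 (SE 0.0088 over 390 probes), and its sons, offspring 2 and offspring 3, were both at −0.12 (SE 0.0067 and 0.0068). The median of the 10 females exceeded that of the 10 males by 0.24. A two-sided permutation test of the means gave p = 1e-05, the smallest that 100000 permutations can give. That test took the arrays as independent, although they hold relatives and all arrays of a sex share its reference. Its p therefore does not test a difference between female and male animals. On the 1 slide that held animals of both sexes, the APA family 2 dam was at 0.32 and the 2 males at 0.090 and 0.089. Female and male self hybridisations were at 0.079 ± 0.010 (n = 3) and 0.066 ± 0.0052 (n = 4). The difference was 0.013 (two-sided exact permutation test, p = 0.0286, the smallest its 35 splits allow). These arrays repeat the reference of each sex and lay on different slides by sex, so the p measures only the spread between arrays.

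In the distal chromosome 14 region 4 animals carried a loss, all of them females of APA families. The APA family 1 dam was at −0.33 and its daughter, offspring 1, at −0.33. The APA family 2 dam was at −0.34 and its daughter offspring 1 at −0.32, each with an SE of 0.0068 to 0.0069 over 429 probes. The other daughter of APA family 2 was at 0.055, and no control animal was below 0.047. The self hybridisations were at 0.052 ± 0.0076 (female, n = 3) and 0.041 ± 0.0084 (male, n = 4). Both sires of the APA families were above 0, at 0.075 and 0.058.

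A loss with fewer probes, on chromosome 7 from 20972970 to 23442363 (11 probes), was carried by the APA family 2 sire, at −0.29 (SE 0.042), and called in its daughter offspring 1, at −0.26 (SE 0.033). The other daughter had a mean of −0.24 (SE 0.035) without passing the calling rule, and the son was at 0.043 (SE 0.025). The dam of that family was at −0.013. In the self hybridisations the mean was 0.018 in females and −0.012 in males.

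**Figure D1:**
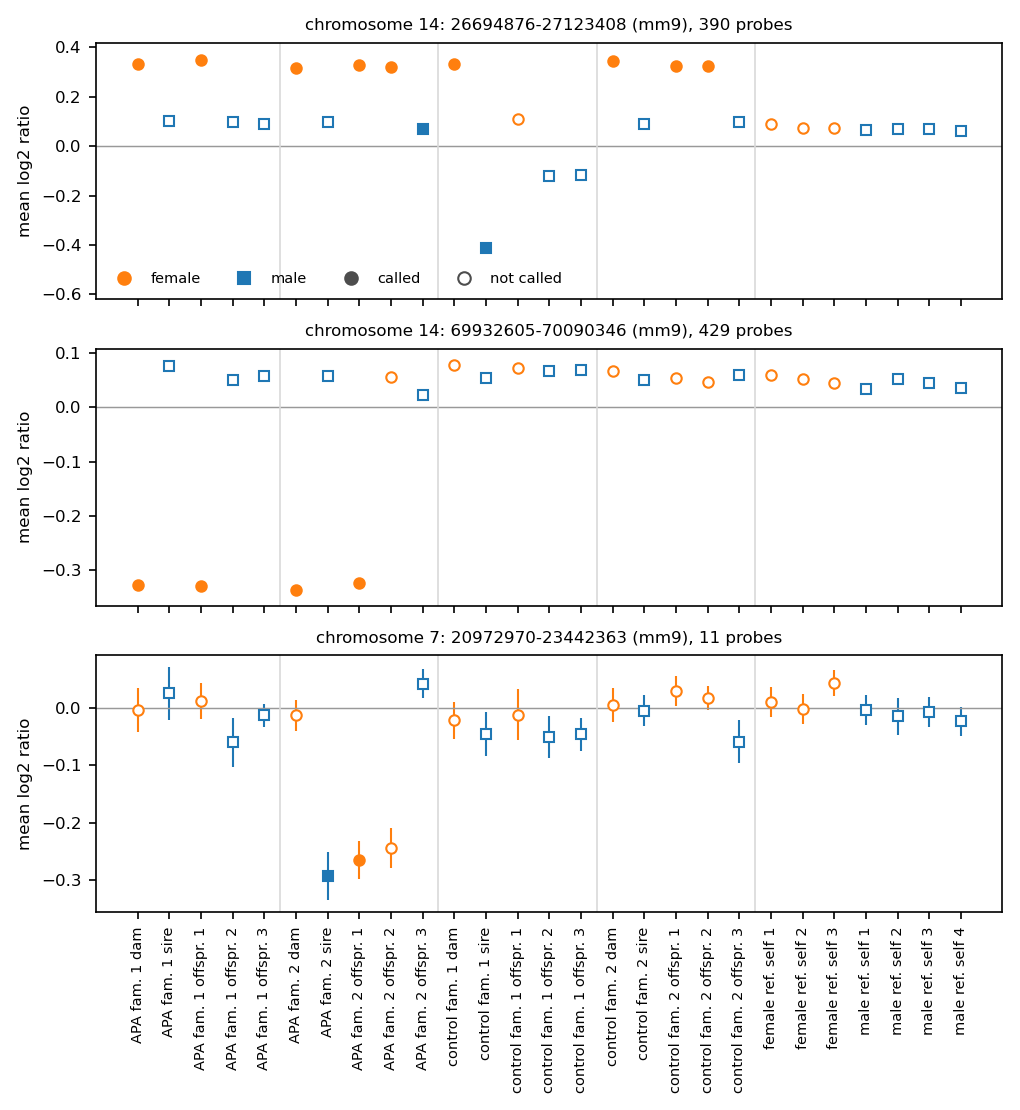
Mean log2 ratio of animal over same-sex reference in the chromosome 14 regions and the chromosome 7 region (mm9) for each of the 27 arrays, with the SE over probes as bars; filled symbols are arrays with a call overlapping the region, circles are females and squares males. At the distal chromosome 14 region 4 females of APA families lie near −0.33, and at the proximal region the control family 1 sire lies at −0.41.

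**Figure D2:**
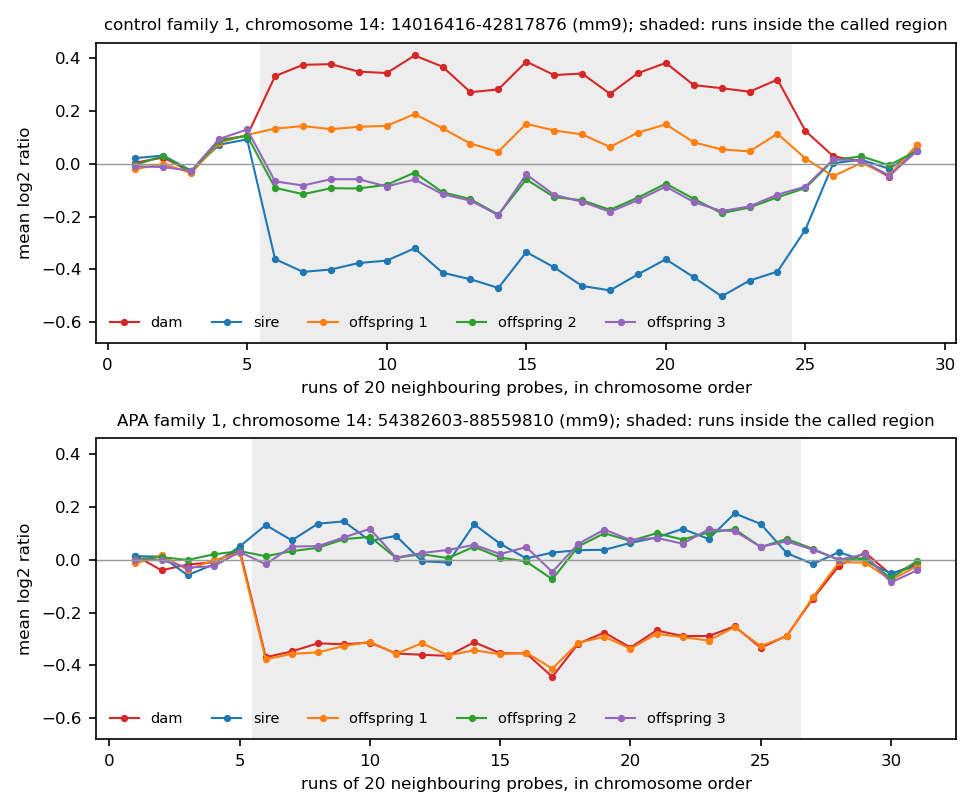
Mean log2 ratio of successive runs of 20 probes along chromosome 14 (mm9) for the members of control family 1 (top, proximal region) and APA family 1 (bottom, distal region); each line is 1 animal and shading marks runs inside the called region. In the upper panel all 3 offspring lie between the dam and the sire, and in the lower panel offspring 1 follows the dam.

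The other regions among the 10 called most often were shorter or close to the background. Losses on chromosome 13 from 116670132 to 116707735 (6 probes) and on chromosome 6 from 74923604 to 74924803 (5 probes) were called in 4 and 3 animals. All of these were males, on 2 slides that held only male arrays. The median of the female animals was −0.17 on chromosome 13 and −0.27 on chromosome 6, against −0.29 and −0.26 in the male animals. Gains on chromosome 5 from 32674875 to 33637148 (33 probes) and on chromosome 2 from 154112940 to 154113816 (6 probes) were called in 3 animals each. A gain on chromosome 17 from 36291740 to 36299734 (9 probes) was called in the APA family 1 sire alone, at 0.36 against 0.12 in the male self hybridisations. After subtraction of the self hybridisations the chromosome 13 loss was called in 1 animal, and the regions on chromosomes 2, 5, 6 and 17 in 0.

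The number of calls did not pass the test between APA and control offspring, and the size and sign of the difference depended on the settings. The 6 APA offspring had 23 calls, or 3.83 ± 2.40 per animal, and the 6 control offspring 20, or 3.33 ± 1.21 (SD). The difference of 0.50 was within the spread (two-sided exact permutation test, p = 0.805). In the main setting 4 APA and 2 control offspring had a call in the proximal chromosome 14 region, where the log ratio followed sex. The control family 1 offspring 1, a female, was at 0.11 there and had no call. Each self hybridisation holds the same DNA in both channels, so subtracting it cannot remove a difference between the female and the male reference. With the self hybridisations subtracted, 12 calls in APA and 3 in control offspring were left. That was 2.00 ± 2.10 and 0.50 ± 0.55 per animal, a difference of 1.5 (two-sided exact permutation test, p = 0.206). Of the 12, 5 were in the APA family 1 offspring 1 and 4 in the APA family 2 offspring 1. In the main setting both of these daughters carried the distal chromosome 14 loss, which was also called in their dams. With the same-sex animal median subtracted, a setting chosen after the data had been seen, there were 5 and 1 (two-sided exact permutation test, p = 0.455). The distal chromosome 14 loss counts as 2 adjoining calls in each carrier; with adjoining calls joined, also chosen after the data had been seen, the totals were 21 and 20, a difference of 0.167 (two-sided exact permutation test, p = 1). With an absolute mean log2 of 0.15 they were 43 and 44, a difference of −0.167. The highest number, 8, was in the APA family 1 offspring 1, a female with the distal chromosome 14 loss and a proximal chromosome 14 gain. Without that animal the APA mean was 3.00 and lay below the control mean, with a difference of −0.333. Sires had 3.5 calls per animal in both arms, and dams 3.5 in the APA and 3 in the control families. The 7 self hybridisations held 3 calls in all.

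By litter, the APA families had 14 and 9 calls and the control families 9 and 11; with 2 litters in each arm an exact permutation test cannot go below p = 0.333. In the 4 pairs of offspring that shared a slide, APA minus control was 5, 1, 0 and −1. Under normexp background correction, which models local background from the spot medians, the totals were 112 and 17, of which 89 were in the APA family 2 offspring 2 alone; the difference of 15.8 per animal was not past the threshold (two-sided exact permutation test, p = 0.0779).

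**Figure D3:**
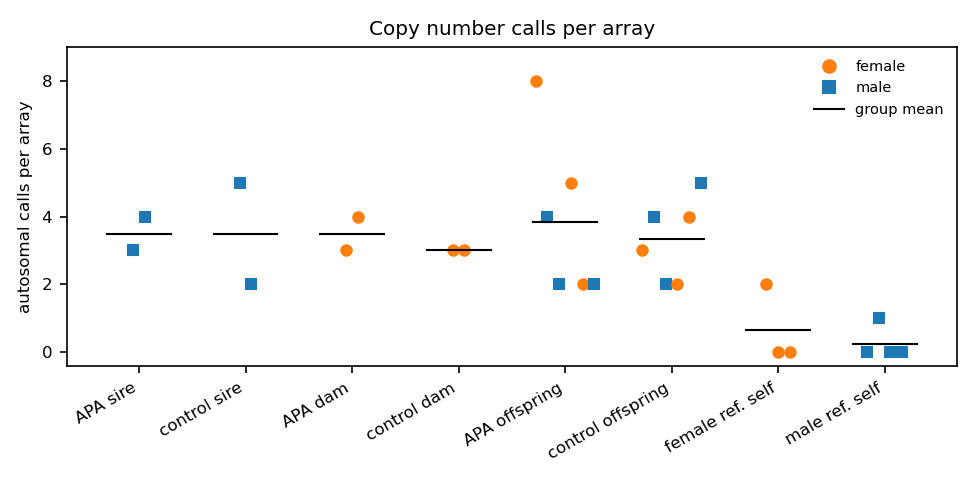
Autosomal copy number calls per array by group; each symbol is 1 array, circles are females, squares are males and the line is the group mean. APA offspring range from 2 to 8 calls and control offspring from 2 to 5, and the self hybridisations hold 0 to 2.

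A call absent from both parents was found in 1 of the 12 offspring. It was a gain on chromosome 17 from 30767613 to 30768794 (mm9, 5 probes) in the control family 2 offspring 2, at 0.30 (SE 0.045), where the sire was at −0.027, the dam at 0.018 and the female self hybridisations at 0.057. Among the 10 female animals, the called one included, the mean over these probes ranged from −0.16 to 0.34, without single probes pulled in. The median of the other females was 0.042. APA offspring had 0 such calls, a difference of −0.167 per animal; with 1 such call in all, the two-sided exact permutation test can only give p = 1 and does not compare the arms. The direction turned with normexp, where APA offspring had 3 and control offspring 0 such calls, and with the self hybridisations subtracted, where they had 1 and 0. With normexp the value of this call turned to −0.26. When a parent was excluded by its call alone, and not also by its mean, 6 calls in APA offspring and 8 in control offspring counted as absent from the parents, with a difference of −0.333 per animal (two-sided exact permutation test, p = 0.792).

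Of the 43 calls in offspring, 29 were also called in the sire or dam of the same animal. Of these 29, 11 were the chromosome 11 gain also seen in the self hybridisations, and 6 lay in the proximal chromosome 14 region, where the log ratio followed sex. Seen from the parents, 31 of 81 combinations of a parental call and an offspring of that parent were shared, or 38.3% (exact Clopper-Pearson 95% interval 27.7 to 49.7%). In offspring of the other families the same parental calls were found in 79 of 243 combinations, or 32.5%. The interval takes the combinations as independent, although siblings and parental calls recur in them, so it does not test this difference. The shares were 38.1% for APA parents and 38.5% for control parents. By family they were 50% and 29.2% in APA and 20.8% and 66.7% in control families. For the same parental calls in other families they were 33.3%, 29.2%, 22.2% and 53.3%. In control family 1 the sire gave 15 of the combinations, of which 1 was shared. Its loss in the proximal chromosome 14 region was split into several calls. Its offspring there, at 0.11, −0.12 and −0.12, missed the calling threshold of 0.25, so their lower values did not count as shared. Reassigning the 12 offspring to the 4 litters in all 369600 ways gave a mean of 27.5 shared combinations against the observed 31 (one-sided exact permutation test, p = 0.0388). That test was chosen after the data had been seen. Its p was 0.213 with the self hybridisations subtracted, where 8 of 63 combinations or 12.7% were shared, and 0.182 with the same-sex animal median subtracted.

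No autosomal probe and no region of neighbouring probes passed the test between the 6 APA and the 6 control offspring. With limma, adjusting for sex and with the litter as a random block, 0 of 26636 probes and 0 of 929 regions passed an adjusted p of 0.05; 1315 probes and 22 regions had an unadjusted p under 0.05. Without the control family 1 offspring 1, 1 probe passed, on chromosome 9 from 101392091 to 101392150. The largest positive differences, APA minus control, lay in the proximal chromosome 14 region, at 0.15 (SE 0.060, 4 probes from 26944877 to 26953407) and 0.11 (SE 0.042, 385 probes from 26694876 to 26833552). Over the 390 probes the control family 1 offspring were at 0.11, −0.12 and −0.12, and the control family 2 offspring at 0.32, 0.33 and 0.098, next to 0.32 to 0.35 in APA daughters and 0.070 to 0.099 in APA sons. The largest negative one was the distal chromosome 14 region at −0.14 (SE 0.060, limma adjusted p = 0.965), where APA offspring were at −0.078 ± 0.19 and control offspring at 0.061 ± 0.0099 (SD, n = 6 each) and 2 APA daughters were at −0.33 and −0.32 and the other 4 APA offspring between 0.022 and 0.057.

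The other regions named by rule were small in size. On chromosome 17 the region from 13311524 to 13322992 (3 probes) was higher by 0.077 and that from 18736754 to 18737992 (3 probes) by 0.050. On chromosome 7 the region from 10678847 to 10685078 (4 probes) was higher by 0.043. Values were −0.042 on chromosome 5 from 26396830 to 26397379 (3 probes), −0.033 on chromosome 4 from 154259063 to 154265739 (36 probes), −0.030 on chromosome 8 from 22233117 to 22239860 (3 probes) and −0.030 on chromosome 17 from 36898082 to 36899744 (3 probes). All had a limma adjusted p of 0.965. In data simulated for this comparison, each of 200 altered regions or probes was shifted in all 6 APA offspring. A shift of 0.1 was then recovered in 94.5% of the regions and 7.5% of the probes, and a shift of 0.2 in 100% and 92.5%. The 200 were a far larger share of the 929 regions than of the 26636 probes, which eases the adjusted threshold for regions. Recovery when only a few regions are altered was not simulated. A change in only some of the offspring was not simulated. The distal chromosome 14 loss, called in 2 APA offspring, did not pass in the real data.

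Between the 2 APA and the 2 control sires the proximal chromosome 14 region gave the largest difference, 0.34 (SE 0.17, 4 probes) and 0.26 (SE 0.12, 385 probes), where the control family 1 sire carried the loss and the control family 2 sire was at 0.089 over all 390 probes. None of the 929 regions passed the test with limma (78 at an unadjusted p under 0.05). The next positive differences were 0.15 on chromosome 7 from 67741932 to 67748605 (5 probes), 0.14 on chromosome 1 from 172994195 to 173005104 (6 probes) and 0.13 on chromosome 12 from 104954138 to 104954842 (4 probes). The negative ones were −0.12 on chromosome 6 from 57426960 to 57429288 (3 probes), −0.10 on chromosome 4 from 113309482 to 113317728 (3 probes) and −0.094 on chromosome 6 from 68620566 to 68626476 (6 probes). They also took in −0.091 on chromosome 4 from 146911995 to 146915076 (7 probes) and −0.091 on chromosome 14 from 54173454 to 54174602 (3 probes). Without the APA family 2 sire, 79 regions passed (61 higher, 18 lower), and the remaining APA sire was the animal array with the highest noise, 0.131. Without the control family 2 sire, 2 passed, both in the proximal chromosome 14 region, at 0.75 and 0.55.

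Between the 2 APA and the 2 control dams, which the labels give as 3 months old, the distal chromosome 14 region differed most, with −0.33 ± 0.0072 in APA dams and 0.072 ± 0.0083 in control dams (SD), a difference of −0.40 (SE 0.090, limma adjusted p = 0.343). Lower values in APA dams were also seen on chromosome 4 from 41643749 to 41650298 (−0.14), on chromosome 1 from 172994195 to 173005104 (−0.12), on chromosome 11 from 3026905 to 3054786 (−0.12) and on chromosome 5 from 33066839 to 33085483 (−0.10). The positive differences reached 0.12, on chromosome 6 from 130494840 to 130498393 (3 probes). They were 0.11 on chromosome 11 from 27745741 to 27746051 and on chromosome 4 from 113309482 to 113317728, 0.090 on chromosome 6 from 131076920 to 131078306 and 0.088 on chromosome 7 from 93710990 to 93713367. With limma 0 of the 929 regions passed, and 43 had an unadjusted p under 0.05. With normexp background correction 266 had an unadjusted p under 0.05, and 0 passed.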

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

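The slide tests of both chromosome 14 regions and the inheritance test were chosen after the result had been seen; the tests of the Cy3 and Cy5 signals were fixed after the log ratios had been seen and before those signals were read.

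The proximal chromosome 14 region had a higher log ratio in females than in males. In the Cy3 channel, which holds the reference, the median over the region on arrays with the female reference minus that on arrays with the male reference was −0.239, about the whole log ratio difference. In the Cy5 channel, which holds the animals, the medians of females and males differed by 0.0059. The means were 1.36 ± 0.067 in females and 1.29 ± 0.16 in males (SD, two-sided permutation test of the means, p = 0.249). The test took the animals as independent, although they are relatives. The tables therefore argue against a difference between the sexes of the animals as large as that of the log ratio. The self hybridisations showed the same gap in both channels, −0.217 for Cy3 and −0.204 for Cy5 (two-sided exact permutation test, p = 0.0286 each). They repeat the reference of each sex, with no slide holding both sexes of them, so the p measures only the spread between arrays. Both channels of such an array hold the same DNA and are not independent. The APA family 2 dam exceeded the highest male on its slide by 0.229, against a slide difference. A candidate explanation is therefore that the female reference DNA held fewer copies than the male reference DNA, which would make the 9 female calls there a property of the reference; no DNA of the references was tested by another method.

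In the same region the 3 offspring of the control family 1 sire differed from the other offspring of their sex by a mean of −0.21 (SD 0.0071), and the sire lay at −0.41. Of the 90 ways to assign the family to offspring within sex, a share of 0.0111 gave a difference as large, the smallest share possible. The Cy3 signal differed by 0.028 and the Cy5 signal by −0.18, which argues against a cause in the reference channel, and the APA family 2 sire, on the slide of both sons, was at 0.097. The Cy5 signal was 0.89 in the sire, 1.38 in the dam, and 1.19, 1.19 and 1.21 in the offspring. Inheritance of a lower copy number from this sire is consistent with these values; it was found and tested on the same data.

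The distal chromosome 14 region differed between the 2 APA dams and the 2 control dams by −0.40, APA minus control. The Cy5 signal differed by −0.44, and the Cy3 signal by −0.029, which raises the log ratio and works against the difference; the lowest of the 6 other arrays on the slides of these dams was at 0.034, so the tables argue against the reference channel and the slide. A copy number difference between the dams stays open as a hypothesis, and 1 daughter in each APA family may have inherited it, since offspring 1 of both families had a mean near that of the dam. Both APA sires were above 0 in this region.

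Of 67 combinations of a group and a measure, 7 held a sample far from the others. Chance gives about 1 in 20 for continuous values; that rate does not apply to 2 of the 7, which are a count of 1 among counts of 0. The noise of the APA family 2 offspring 3 was 0.118 against at most 0.107 in the other APA offspring. The male self hybridisation 2 had 1 call where the other 3 had 0, and the control family 2 offspring 2 had 1 call absent from both parents where the other 5 control offspring had 0. On chromosome 5 from 32674875 the control family 1 offspring 1 was at 0.26, next to 0.22. On chromosome 2 from 154112940 the control family 2 offspring 3 was at 0.27, next to 0.24. On chromosome 14 from 26944877 the male self hybridisation 4 was at 0.028, next to −0.012. On chromosome 5 from 26396830 the APA family 2 offspring 3 was at −0.053, next to 0.080.

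Outside the autosomes used for the comparisons, 2 calls were made in animals and 0 in self hybridisations. Both were gains on the Y chromosome in females, where the animal and the reference lack a Y: 0.26 over 9 probes from 61333 to 64093 in the APA family 2 dam, and 0.30 over 6 probes from 1559961 to 1573857 in the APA family 2 offspring 1. None of 23 measures had an APA effect that differed between female and male offspring at an exact p under 0.05; the closest was the chromosome 7 region from 20972970, at −0.18 in females and 0.042 in males (exact permutation test, p = 0.05, adjusted p = 0.761).

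The count of 0 probes and 0 regions between APA and control offspring was set against 100 of the 462 splits of the 12 offspring. With a real count of 0 all 100 must give at least as many, so these counts carry no information on chance. The highest other split gave 518 probes, and it was the split of the 6 females from the 6 males. Of these probes 344 lay in regions of neighbouring probes anywhere on chromosome 14, not only in the proximal and distal ones. For regions the highest was 52, in a split that put 5 of the 6 females on one side. In the first of these the groups coincide with sex, which was then no longer adjusted for, so it points to a structure of the samples by sex and by reference. At an unadjusted p under 0.05 the real grouping had 1315 probes and 22 regions. At least as many were found in 42 and 68 of the 100 splits, the real one included.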

How the results depend on the processing

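Subtraction of the same-sex animal median, joining of adjoining calls, and subtraction of the self hybridisations for the parental share were chosen after the data had been seen. The cause of a change was not tested unless the setting itself gives it. The count of differing probes between APA and control offspring was 0 in every fit except those that left out 1 offspring, which gave 0 to 1 (without the control family 1 offspring 1, 1 probe on chromosome 9 from 101392091, with a difference of −0.41). The count of regions was 0 in every fit except 3 with the family number as a replicate block, each of 2 probes and higher in APA offspring by 0.044 (chromosome 11 from 48814594), 0.044 (chromosome 6 from 70467634) and 0.048 (chromosome 7 from 16172529); that fit was planned, and its regions, which lie outside the naming rule, were chosen for naming after their values were seen. The families of the arms share only a number; the difference between family 1 and family 2 correlated at 0.474 between the arms over regions and at 0.385 after the same-sex animal median was subtracted, and both arms had 1 female in family 1 and 2 in family 2. For sires the count was 0 except when 1 sire was left out (0 to 79, the lone sire being assumed to vary like the other groups). The sire difference on chromosome 14 then ranged from −0.065 to 0.75 from 26944877 and from −0.025 to 0.55 from 26694876.

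The difference in calls per offspring was positive except with an absolute mean log2 of 0.15 (−0.167) and in 1 of the leave-one-out values, which ranged from −0.333 to 0.867. Against 0.5 in the main setting it was 1.5 after subtraction of the self hybridisations (12 against 3 calls), 15.8 with normexp, 0.833 with at least 10 probes and 0.667 with the same-sex animal median subtracted; it was 0.167 with adjoining calls joined and with an absolute mean log2 of 0.4. The replicate block left its p at 0.805. Calls absent from both parents gave a difference of 0.5 with normexp and 0.167 after subtraction of the self hybridisations. It was 0 with at least 3 probes, at least 10 probes, an absolute mean log2 of 0.4, a doubled penalty or the same-sex animal median subtracted, and −0.2 to 0 without 1 offspring each. The parental share was 12.7% after subtraction of the self hybridisations, 50% with at least 10 probes, 0% with an absolute mean log2 of 0.4 and 7.69% with the same-sex animal median subtracted. The noise difference ranged from 0.0029 to 0.0062 without 1 offspring each, and without the control family 1 offspring 1 it passed the threshold (0.0062, exact permutation test, p = 0.0498).

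Among the named values, the chromosome 8 difference from 22233117 turned to 0.018 with normexp, the sire difference on chromosome 4 from 146911995 to 0.0091 with the slide as a term, and the chromosome 17 call from 30767613 to −0.26 with normexp. Of the values of named offspring regions under the other settings, 212 kept their sign and their side of the threshold. With 2 litters in each arm the litter totals could not pass it. The alternatives for gene lists were not run, as no gene names were used. Signal over background was high on every array, and what else limits the comparisons was not tested. A shift of 0.1 in all 6 APA offspring was recovered in 7.5% of simulated probes and 94.5% of simulated regions. The 94.5% holds for 200 altered regions among 929, and a smaller number of altered regions was not simulated. A change in only some of the offspring was not simulated.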

Other observations

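The columns of the authors' table were matched to the arrays before any region was called; the comparison of region means was made after the regions had been seen.

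In the authors' table of log2 ratios 818 probes lay on chromosome 14, 15 on chromosome 4 and 11 on chromosome 7. Of its probes 838 fell into 4 of the regions called from the scanner values: 390 in the proximal and 428 in the distal chromosome 14 region, 11 in the chromosome 7 region and 9 in the chromosome 4 region from 41643749. In the authors' table the control family 1 sire was at −0.41 in the proximal region, and the APA dams of families 1 and 2 were at −0.33 and −0.32 in the distal region. The chromosome 7 loss was at −0.28 in the APA family 2 sire, −0.26 in offspring 1 and −0.24 in offspring 2. The largest difference of a region mean between the authors' table and the scanner values was 0.129. It lay in the chromosome 4 region, in the APA family 2 offspring 3, at 0.30 in the authors' table and 0.17 in the scanner values. There, every array on the slides that held only male arrays was higher in the authors' table, by 0.064 to 0.129. Arrays on the other slides differed by at most 0.015. In the other regions the largest difference was 0.033. The cause was not tested.

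The chromosome 11 gain from 3026905 was present in animals and self hybridisations alike. The female animals had a median of 0.30 and the male animals 0.27, against 0.25 and 0.19 in the self hybridisations. Self hybridisations also held a gain on chromosome 1 from 172994195 to 173016108 (8 probes), called at 0.25 with the female and 0.28 with the male reference.

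On the Y chromosome, the 52 probes had a median log2 between −0.038 and 0.122 over the animals, with the highest values in 2 females, the APA family 2 dam (0.12) and the control family 2 dam (0.11). Under normexp the APA family 2 dam had 70 calls and the APA family 2 offspring 2 had 89.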
